A study of Mus musculus with 14 samples.

How the data were processed

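Total RNA of mouse embryonic fibroblasts was sequenced in 14 libraries, which the labels place in 4 groups by genotype and medium. The cells came from embryos of day 14.5, were used at passages 3 to 4, and spent 18 hours in normal or glucose-free medium before harvest. The 4 groups are wild type in normal medium (WT-NT, n = 4), wild type in glucose-free medium (WT-GS, n = 3), SirT7-/- in normal medium (KO-NT, n = 4) and SirT7-/- in glucose-free medium (KO-GS, n = 3). Libraries are named by group and replicate number, as in KO-NT 4. The labels do not say whether replicates are separate cultures or embryos, so the p-values measure the spread between these samples.

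Per the submitters' processing notes, the reads went through FastQC 0.11.3, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools and StringTie 1.3.3 on genome build mm9, followed by DESeq2 1.18.1. The annotation, read length, pairing and strand setting are not stated. The deposited table holds estimated counts, as whole numbers, for 24015 gene symbols in the 14 libraries. Small values from 2 to 11 were odd in 53.5 to 61.7% of cases per library, so the values are not a plain tally of reads. The table was used with no further scaling of its values. In 27 entries a date stands in place of a gene symbol, and 4225 genes had 0 in all libraries. Genes are given by symbol, because the table holds no positions. Gene order on the chromosome came from a RefSeq annotation of another genome build than the one the submitters named, and served only to find neighbouring genes.

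Total counts per library ran from 59788270 (WT-GS 2) to 91607861 (KO-NT 4). A count of 0 allows a level of up to 0.0502 CPM, the count scaled to the library's total, in the shallowest library, taking 3 counts as the limit. Such limits cover counting error only.

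Counts were fitted with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust dispersion, TMM normalization, and 1 mean per group over all 14 libraries. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 15666 genes. The 5 comparisons are starved against normal medium in each genotype, SirT7-/- against wild type in each medium, and the difference between the genotypes' responses. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 changes are given with a standard error (SE) worked back from the F-test, whose spread is shared over all libraries of the fit. The SE is therefore not the spread of the groups compared alone. Levels are given as mean CPM ± SD. A positive change means higher in starved, or in SirT7-/-, samples.

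From general knowledge, 41 gene lists of pathways, cell types and control genes were written, and 38 had at least 5 measured genes and received a set test. Of 1067 list entries, 1053 were matched to the table. Each list was tested with camera (limma 3.58.1) on log-CPM values (prior count 2) with a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. These p-values were adjusted over the 38 lists of a comparison. With an estimated correlation, no list was called in any comparison. Single genes were also adjusted over the list alone.

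The rule for named genes admits Sirt7 throughout. For each comparison it admits the 10 largest rises and the 10 largest falls among called genes with a group mean of at least 5 CPM and no overlap between the libraries of the groups compared. It leaves out features with no symbol and predicted or clone symbols. It also admits up to 4 members per list with the smallest p, any member where a list is described by count, and the sex-linked, marker and Sirt7-neighbour genes as controls. Groups, tests, lists, this rule and the alternatives below were set before the data were examined.

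The alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, library size alone, no filter, a stricter filter (1 CPM in all libraries of a group and a mean count of 50), a fit on only the groups compared, replicate number as a block, and leaving out each library in turn. Further alternatives were chosen after seeing the data. They leave out the 2 libraries labelled KO-NT 4 and KO-GS 3, or these and WT-NT 4, and the rule for named genes was also applied to the fit without the 2 libraries, which tested 15864 genes. The analysis was tested on simulated data with shifted genes and a shifted list. No library or gene of the table was left out for any other reason than the filter.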

Results

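The data are gene-level RNA counts from 14 libraries of mouse embryonic fibroblasts, primary connective-tissue cells grown from the embryo. SirT7 is a sirtuin, an enzyme family that uses NAD, and the series asks how its loss bears on the response of these cells to glucose starvation. The libraries comprise 4 of WT-NT, 3 of WT-GS, 4 of KO-NT and 3 of KO-GS. Total counts lay between 59788270 and 91607861, and 16656 to 17386 genes had a count in a given library. The 10 most abundant genes took 6.84 to 8.63% of the counts.

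Sirt7 itself was low in every library labelled SirT7-/-, at 0.301 to 1.41 CPM against 16.9 to 23.1 CPM in the wild-type libraries. Placement by medium was less uniform. Along 5160 genes called for starvation in a fit on the wild-type libraries alone, with 0 at the mean of WT-NT and 1 at the mean of WT-GS, the libraries KO-NT 1 to 3 lay between -0.0148 and 0.0579 and KO-GS 1 and 2 between 0.873 and 0.903. The library labelled KO-NT 4 lay at 0.85 and the library labelled KO-GS 3 at 0.186. WT-NT 4 lay at 0.183, the highest of its group. All comparisons below use the groups as labelled, and the count of called genes in each comparison is also given without the 2 libraries labelled KO-NT 4 and KO-GS 3. Where a paragraph uses only the fit without them, it says so.

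**Figure D1:**
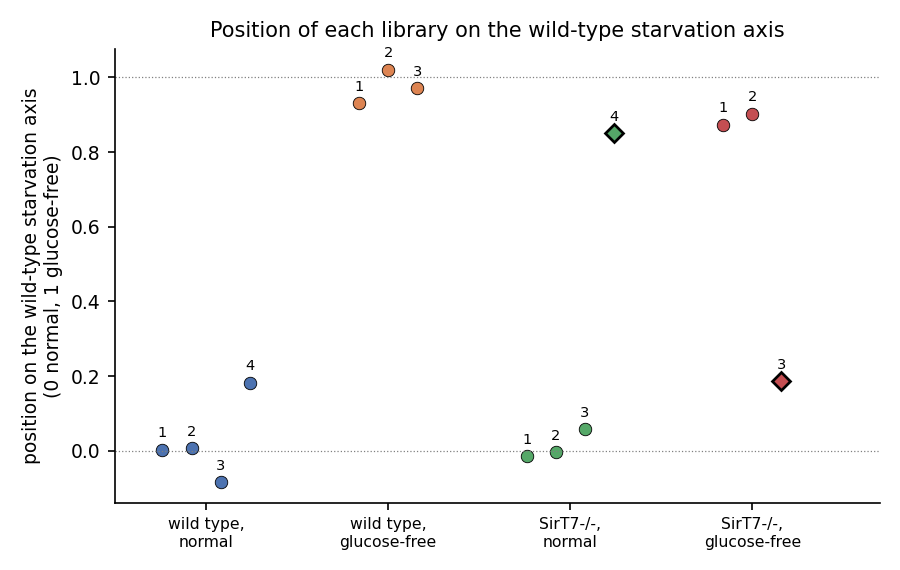
Position of each library along the genes that wild-type cells changed on starvation, with 0 at the WT-NT mean and 1 at the WT-GS mean, and each dot 1 library. The library labelled KO-NT 4 sits at 0.85, with the starved libraries, and the library labelled KO-GS 3 at 0.186, with those in normal medium.

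The first comparison asks which genes wild-type fibroblasts change after 18 hours without glucose. Most listed chaperones and folding factors of the endoplasmic reticulum rose, while most listed genes of sterol synthesis and cell division fell. Hspa5, the main chaperone of that compartment, rose from 1362 ± 199 CPM (SD, n = 4) to 6712 ± 642 CPM (SD, n = 3). Txnip, a glucose-responsive inhibitor of glucose uptake, fell from 169.7 ± 34.3 CPM to 3.61 ± 1.77 CPM. Of 15666 genes tested, edgeR called 4063, or 25.9%, with 2014 higher and 2049 lower in starved cells, and 521 and 968 of these changed at least 2-fold. The count was 6280 without the 2 libraries labelled KO-NT 4 and KO-GS 3, and 4055 of the 4063 genes were called in both fits. The smallest adjusted p by edgeR was 0.0245 with all libraries and 4.77e-07 without the 2. An edgeR fit on only the wild-type groups called 5161 genes, with a smallest adjusted p of 6.59e-05. In the fit on all groups the count moved when single libraries were left out: it was 0 without WT-NT 3, WT-GS 1 or WT-GS 2, 1 without WT-GS 3, 1371 without WT-NT 1 and 2064 without WT-NT 2. With none called, edgeR still gave 5752, 5312 and 5585 genes at an unadjusted p under 0.05 in the first 3 of these fits. All of these fits share their spread with the libraries labelled KO-NT 4 and KO-GS 3. Of the wild-type libraries, only WT-NT 4 was also left out of a fit without those 2. The counts therefore cannot show how far the wild-type response itself rests on 1 library. With all libraries, DESeq2 called 5624 genes and limma-voom 3620, and scaling by library size alone gave 3988, with 1496 higher and 2492 lower.

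Among the genes with the largest rises, Derl3, which acts in the removal of misfolded proteins from the endoplasmic reticulum, had a log2 change of 8.10 (SE 2.42, adjusted p = 0.0336). Its level went from 0.34 ± 0.148 CPM to 91.5 ± 30.9 CPM. The other largest rises were Wnt7a, Slc6a12, Car6, Prr32, Clic5, Ero1lb, Ano1, Dnajb9 and Extl1, with log2 changes from 6.87 for Wnt7a to 3.64 for Extl1. Ero1lb, an oxidase that helps form disulfide bonds, rose from 3.64 ± 0.776 to 53.7 ± 7.41 CPM, and the co-chaperone Dnajb9 from 26.8 ± 8.82 to 325 ± 45.3 CPM. The largest falls were Adamts16, Ccr2, Txnip, Apol6, F13a1, Col24a1, Lrrc17, Cxcl5, Ifitm1 and Omd, with log2 changes from -7.19 (SE 1.75, adjusted p = 0.0245) for Adamts16 to -3.99 (SE 1.27, adjusted p = 0.0394) for Omd. Ccr2 and F13a1 are also expressed by macrophages, whose marker genes differed between libraries.

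**Figure D2:**
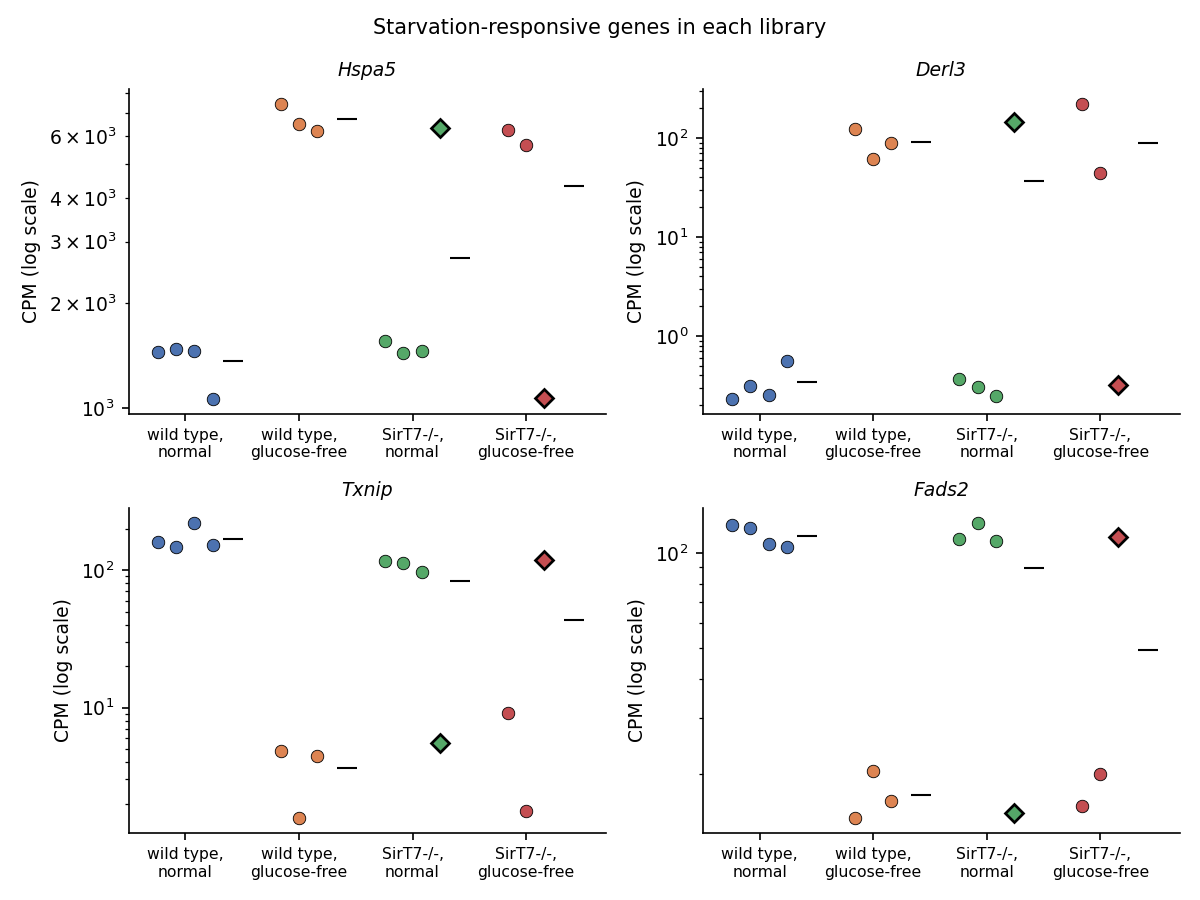
CPM on a log axis of Hspa5, Derl3, Txnip and Fads2 in the 4 groups, with each dot 1 library, each dash a group mean, and diamonds for the 2 libraries labelled KO-NT 4 and KO-GS 3. Hspa5 averages 1362 CPM in WT-NT and 6712 CPM in WT-GS, and the diamonds lie with the other medium's libraries.

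Of the 24 measured genes on the list of endoplasmic reticulum chaperones, 22 were higher and 0 lower, and 23 were higher when adjusted over the list alone (camera adjusted p = 1.35e-08; adjusted p = 0.678 with an estimated correlation). Hsp90b1 changed by 2.36 (SE 0.609) and Canx by 1.31 (SE 0.334) on the log2 scale. Of 35 targets of the integrated stress response, which includes amino acid synthesis and transport genes, 14 were higher and 2 lower, or 18 and 4 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.678 with an estimated correlation). The amino acid transporter Slc7a1 rose from 162 ± 21 to 385 ± 21 CPM and the serine synthesis gene Psph changed by 0.98 (SE 0.262), while Sesn2 changed by -0.38 (SE 0.1) and Atf5 by -0.50 (SE 0.133). Of 20 transfer RNA synthetases, 10 were higher and 1 lower, or 12 and 2 adjusted over the list alone, with Qars at 0.56 (SE 0.15). The camera adjusted p of that list was 0.00646, and adjusted p = 0.678 with an estimated correlation. Without WT-NT 4 it was 0.0964, in a range of 0.00234 to 0.0964 over the alternatives. The estimated correlation draws on the spread within all groups, including the 2 SirT7-/- libraries that lay with the other medium. Its adjusted p-values for wild type therefore do not rest on the wild-type libraries alone. Over the 38 lists, the smallest was 0.678 with all libraries and 0.157 without those 2, a fit chosen after seeing the data. No list was called in either fit.

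Sterol synthesis genes fell: of 23 measured, 0 were higher and 16 lower, or 20 lower adjusted over the list alone (camera adjusted p = 2.19e-06; adjusted p = 0.678 with an estimated correlation). Their median log2 change was -1.82, and the examples Mvk and Pmvk, kinases of the mevalonate pathway, changed by -1.64 (SE 0.472) and -2.31 (SE 0.654). Of 15 fatty acid synthesis genes, 0 were higher and 10 lower, or 11 lower adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.678 with an estimated correlation). The desaturase Fads2 fell from 113 ± 9.12 to 17.1 ± 3.02 CPM, and Scd2 changed by -2.13 (SE 0.585).

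Of 30 genes of the G2 and M phases of the cell cycle, 0 were higher and 28 lower, and 30 were lower adjusted over the list alone (camera adjusted p = 1.05e-09; adjusted p = 0.678 with an estimated correlation). The mitotic kinase Plk1 fell from 47.1 ± 10.4 to 7.45 ± 1.52 CPM, and the checkpoint gene Bub1b changed by -1.98 (SE 0.477). Of 32 DNA replication genes, 0 were higher and 11 lower, or 15 lower adjusted over the list alone (camera adjusted p = 0.000594; adjusted p = 0.678 with an estimated correlation), with Tyms at -1.11 (SE 0.273) and Mcm5 at -1.11 (SE 0.281). Of 35 extracellular matrix genes, 2 were higher and 12 lower, or 2 and 16 adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.681 with an estimated correlation). Col1a1, a chain of type I collagen, fell from 11853 ± 2759 to 2733 ± 165 CPM and Col1a2 changed by -1.39 (SE 0.321), while the protease inhibitor Timp1 changed by 0.95 (SE 0.187). The camera adjusted p of the matrix list was 0.155 without WT-NT 4, in a range of 0.000912 to 0.155 over the alternatives.

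Genes that glucose itself is known to drive were measured as a list of 7, of which 0 were higher and 2 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.198; adjusted p = 0.681 with an estimated correlation). The 2 were Txnip and its relative Arrdc4, which changed by -2.24 (SE 0.652). Of 20 glycolysis genes, 5 were higher and 1 lower, and the same counts held adjusted over the list alone (camera adjusted p = 0.294; adjusted p = 0.733 with an estimated correlation). Pgk1 changed by 0.63 (SE 0.171) and Hk2 by 0.57 (SE 0.171), while Aldoc changed by -1.70 (SE 0.366). Of 17 hypoxia targets, 6 were higher and 0 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.678 with an estimated correlation). The examples were Ero1l at 1.86 (SE 0.534), which also serves disulfide bond formation, and Ndrg1 at 1.05 (SE 0.31). The hypoxia list's camera adjusted p was 0.0906 without WT-GS 2, in a range of 0.00398 to 0.0906.

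Of 40 ribosome assembly genes, 16 were higher and 2 lower, or 17 and 2 adjusted over the list alone (camera adjusted p = 7.29e-05; adjusted p = 0.678 with an estimated correlation), with Pno1 at 0.67 and Noc3l at 0.79. Of 75 ribosomal proteins, 4 were higher and 0 lower, and 0 passed adjusted over the list alone (camera adjusted p = 1.74e-05; adjusted p = 0.715 with an estimated correlation), with Rpl24 at 0.60 (SE 0.183). Of 39 autophagy and lysosome genes, 12 were higher and 2 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.678 with an estimated correlation). Atg12 changed by 0.86 (SE 0.2) and Becn1 by 0.42 (SE 0.0794), while the lysosomal regulator Tfeb changed by -1.15 (SE 0.27).

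Some developmental and other cell type genes were called as well. Of 38 Hox genes, which carry positional identity, 2 were higher and 9 lower, or 2 and 10 adjusted over the list alone (camera adjusted p = 0.00646; adjusted p = 0.678 with an estimated correlation), with Hoxa7 at -1.38 (SE 0.359). Of 22 imprinted growth genes, 0 were higher and 7 lower, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0501; adjusted p = 0.678 with an estimated correlation). Mest changed by -3.73 (SE 0.883), Peg3 by -1.96 (SE 0.515) and Meg3 by -0.98 (SE 0.201), and the list's camera adjusted p ranged from 0.0203 without WT-NT 3 to 0.205 without WT-NT 4. Of 15 macrophage markers, 0 were higher and 3 lower, or 6 lower adjusted over the list alone (camera adjusted p = 0.000227; adjusted p = 0.678 with an estimated correlation), with Cx3cr1 at -3.87, Mrc1 at -3.21 and Cd14 at -2.54. These markers varied between libraries of 1 group: their mean log2 CPM was 5.60, 3.64, 6.65 and 4.64 in WT-NT 1 to 4, and 3.63, -1.55 and 3.54 in WT-GS 1 to 3. Of 18 skeletal muscle markers, 2 were higher and 6 lower, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.00646; adjusted p = 0.678 with an estimated correlation), with Tnni2 at -3.67 and Acta1 at 1.67. With 1 library left out, Tnni2 ran from -5.561 to -3.153 and Acta1 from 1.032 to 2.023. Tnni2 was scarce, at a mean of 1.04 CPM in WT-NT and 0.0746 CPM in WT-GS, near the limit for a count of 0. Acta1 averaged 36.5 and 113 CPM.

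For the study's own subject, 22 sirtuin, macroH2A and PARP genes were measured, of which 2 were higher and 2 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.88; adjusted p = 0.971 with an estimated correlation). Sirt1 rose from 22.7 ± 0.356 to 35.6 ± 1.78 CPM and Sirt5 changed by 0.72 (SE 0.236). H2afy2, which encodes macroH2A2, fell from 39 ± 12 to 15 ± 1.45 CPM, and Parp8 changed by -0.52 (SE 0.151). H2afy, which encodes macroH2A1, had a log2 change of -0.30 (SE 0.134, adjusted p = 0.109), and its splice forms cannot be separated in gene-level counts. Of 64 second messenger genes, 4 were higher and 12 lower, or 5 and 19 adjusted over the list alone, with Camk2d at 0.57 (SE 0.114) and Pde4a at -1.02 (SE 0.257). That list's camera adjusted p was 0.0823, and adjusted p = 0.678 with an estimated correlation. It was 0.0193 without WT-NT 2, in a range of 0.0193 to 0.234. The list was written knowing what the study is about, so it is not independent evidence of a direction.

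The second comparison asks the same of SirT7-/- fibroblasts. With all 7 libraries as labelled, no gene passed edgeR's test. The library labelled KO-NT 4 held chaperone levels like those of starved wild-type cells, and the library labelled KO-GS 3 did not. Hspa5 averaged 2695 ± 2425 CPM (SD, n = 4) in KO-NT and 4324 ± 2837 CPM (SD, n = 3) in KO-GS. Without those 2 libraries, Hspa5 averaged 1483 ± 63.9 CPM in KO-NT 1 to 3 and 5953 ± 422 CPM in KO-GS 1 and 2. The fit without them was chosen after seeing the data. In it most listed chaperones rose, and most listed sterol synthesis and G2 and M phase genes fell. Camera with an estimated correlation called no list in that fit (smallest adjusted p = 0.0731). With all libraries, edgeR called 0 of 15666 genes, with 2919 at an unadjusted p under 0.05 and a smallest adjusted p of 0.227. DESeq2 called 201, with 23 higher and 178 lower, and limma-voom called 0, with 2912 at an unadjusted p under 0.05. The edgeR count was 3301 without the library labelled KO-NT 4 and 1 without WT-GS 2. Without both libraries it was 5251 of 15864, with 2954 higher and 2297 lower.

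In that fit without the 2 libraries, the largest rises were Derl3, Eif3j1, Wnt7a, Prr32, Car6, B4galnt2, Perp, Clic5, Ppef1 and Tnfsf18. Derl3 changed by 8.74 (SE 0.686, adjusted p = 3.02e-05), against 1.27 (SE 1.82, adjusted p = 0.704) with all libraries. Its adjusted p ranged from 3.02e-05 to 0.896 over the alternatives. Eif3j1, a translation initiation factor, had a log2 change of 7.63 (SE 2.52), but it shares sequence with Eif3j2 and went from near 0 to abundant within groups. The largest falls were Ms4a4d, Adamts16, Cxcl5, Emc6, Lrrc17, Aoc3, Txnip, Col24a1, Eln and Heyl. Txnip fell from 109 ± 10.9 CPM in 3 libraries to 5.48 ± 5.25 CPM in 2 (log2 change -4.32, SE 0.647). Emc6 was 0.424 CPM in WT-NT 1, so its log2 change of -4.68 (SE 1.34) is uncertain. Eln encodes elastin and had a log2 change of -3.66 (SE 0.861).

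In SirT7-/- cells with all libraries, 0 of the members of every list named here were called over all genes. Of the 30 G2 and M phase genes, 0 were called adjusted over the list alone (camera adjusted p = 4.92e-06, median log2 change -0.59; adjusted p = 0.899 with an estimated correlation), and the camera p-values were 0.00438 for the 24 chaperones, 0.00255 for the 23 sterol genes, 1.99e-07 for the 32 replication genes, 2.87e-05 for the 39 autophagy genes and 0.000246 for the 22 p53 targets, each with adjusted p = 0.899 with an estimated correlation. Adjusted over the list alone, 8 replication genes were lower, 10 p53 targets were higher and 1 lower, and 0 of the chaperone, sterol and autophagy genes passed. The chaperone list lost its call without KO-GS 1 (0.468), and the sterol list without KO-GS 1 (0.148) or KO-GS 2 (0.107). For the 35 stress response targets, the median log2 change was 0.05, the mean was -0.01 and camera pointed down (adjusted p = 0.911; adjusted p = 0.996 with an estimated correlation).

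The libraries labelled KO-NT 4 and KO-GS 3 were left out for their position along the wild-type starvation genes. Calls and p-values for starvation genes in every SirT7-/- result without them are therefore partly set by that choice. Without the 2 libraries, 23 of 24 chaperones were higher and 0 lower, or 23 and 1 adjusted over the list alone (camera adjusted p = 7.04e-16; adjusted p = 0.346 with an estimated correlation), with Herpud1 at 2.45 (SE 0.185) and Dnajb9 at 3.76 (SE 0.288). Of 23 sterol synthesis genes, 0 were higher and 21 lower, or 22 lower adjusted over the list alone (camera adjusted p = 3.68e-18; adjusted p = 0.231 with an estimated correlation). Cyp51, an enzyme of that pathway, changed by -2.67 (SE 0.133). Of 15 fatty acid synthesis genes, 0 were higher and 11 lower, or 13 lower adjusted over the list alone (camera adjusted p = 1.02e-08; adjusted p = 0.0731 with an estimated correlation), with Fasn at -1.39 (SE 0.0907) and Fads2 at -2.68 (SE 0.178). All 30 G2 and M phase genes were lower by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 5.5e-16; adjusted p = 0.381 with an estimated correlation), with Plk1 at -2.81 (SE 0.291) and Cdc20 at -2.12 (SE 0.241). Of 32 replication genes, 0 were higher and 13 lower, or 14 lower adjusted over the list alone (camera adjusted p = 3.95e-05; adjusted p = 0.725 with an estimated correlation). Over the alternatives, the camera adjusted p reached 0.468 for chaperones, 0.148 for sterol genes, 0.213 for fatty acid genes, 0.0371 for G2 and M phase genes and 6.21e-05 for replication genes.

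In the same fit, 17 of 35 stress response targets were higher and 3 lower, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.00101; adjusted p = 0.626 with an estimated correlation), with Stc2 at 2.23 (SE 0.154) and Ddit3, a stress-induced transcription factor, at 2.71 (SE 0.219). Of 17 hypoxia targets, 8 were higher and 1 lower, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00565; adjusted p = 0.381 with an estimated correlation), with Bnip3 at 2.03 (SE 0.216) and Pdk1 at 1.39 (SE 0.16). Of 39 autophagy genes, 23 were higher and 2 lower, or 24 and 2 adjusted over the list alone (camera adjusted p = 4.98e-05; adjusted p = 0.595 with an estimated correlation). Of 35 matrix genes, 1 was higher and 15 lower by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 8.82e-05; adjusted p = 0.346 with an estimated correlation), with Col1a1 at -2.23 (SE 0.234). Of 22 p53 targets, 9 were higher and 0 lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0214; adjusted p = 0.725 with an estimated correlation), with Mdm2 at 127 ± 10 CPM in KO-NT 1 to 3 and 288 ± 6.21 CPM in KO-GS 1 and 2. In wild type with all libraries, 4 p53 targets were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.113; adjusted p = 0.729 with an estimated correlation), and camera gave 0.0218 without WT-NT 4, in a range of 0.0116 to 0.237. Of 75 ribosomal proteins, 14 were higher and 0 lower, or 13 higher adjusted over the list alone (camera adjusted p = 0.00988; adjusted p = 0.827 with an estimated correlation). Over the alternatives, the camera adjusted p reached 0.894 for stress response, 0.1 for hypoxia, 0.00156 for autophagy, 0.783 for matrix, 0.0267 for p53 and 0.664 for ribosomal protein genes. Sirt1 changed by 0.63 (SE 0.0906) and Arrdc4 by -2.05 (SE 0.161), while H2afy had a log2 change of -0.20 (SE 0.136, adjusted p = 0.286).

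**Figure D3:**
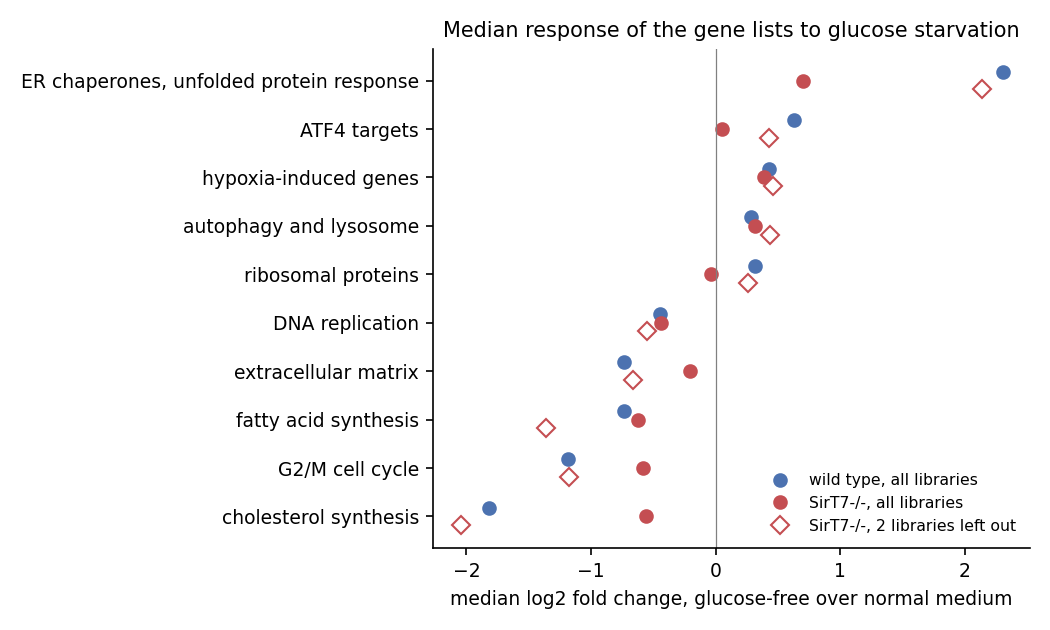
Median log2 change on starvation of 10 gene lists, for wild type with all libraries, SirT7-/- with all libraries, and SirT7-/- without the 2 libraries labelled KO-NT 4 and KO-GS 3. The chaperone median is 2.31 in wild type, 0.70 in SirT7-/- with all libraries and 2.14 without the 2.

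The third comparison asks which genes SirT7 loss changes in normal medium. Sirt7 fell from 20.3 ± 2.41 CPM (SD, n = 4) to 1.09 ± 0.402 CPM (SD, n = 4), a log2 change of -4.18 (SE 0.276, adjusted p = 3.21e-05), and was lower in all 4 SirT7-/- libraries. It was the only gene edgeR called with all libraries, with 658 genes at an unadjusted p under 0.05. Its neighbour on chromosome 11, Pcyt2, which acts in phosphatidylethanolamine synthesis, averaged 67.6 ± 15.5 CPM in WT-NT and 13 ± 3.91 CPM in KO-NT (log2 change -2.35, SE 0.339, adjusted p = 0.0662). Without the 2 libraries labelled KO-NT 4 and KO-GS 3, a fit chosen after seeing the data, 4 genes were called, 2 higher and 2 lower. They were Sirt7, Pcyt2 at -2.16 (SE 0.163, adjusted p = 0.000432), P4hb, a protein disulfide isomerase, at 1.16 (SE 0.133, adjusted p = 0.017), and Zfp36l2, an RNA-binding protein, at 0.53 (SE 0.0618, adjusted p = 0.017). Over the alternatives, the adjusted p of Pcyt2 ranged from 5.63e-09 to 0.341, and those of P4hb and Zfp36l2 from 0.017 to 1. P4hb averaged 1535 ± 150 CPM in WT-NT and 3179 ± 392 CPM in KO-NT, and another neighbour, Arhgdia, had a log2 change of 0.96 (adjusted p = 0.968) with all libraries, and an adjusted p of 0.202 without the 2, in a range of 0.202 to 1. DESeq2 called 19 genes and limma-voom 3. The edgeR count was 2 without WT-NT 4, 2 without the library labelled KO-GS 3 and 3 without KO-GS 2.

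**Figure D4:**
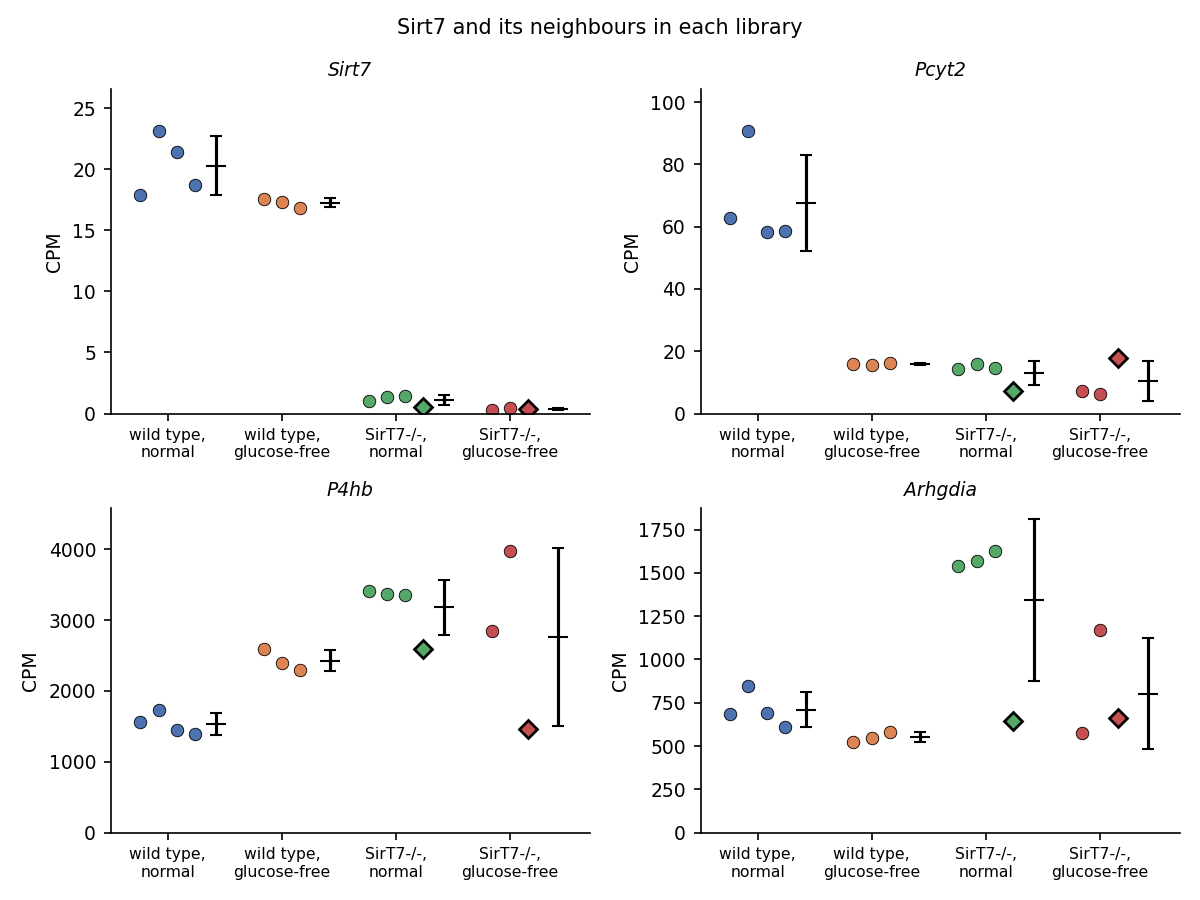
CPM on a linear axis of Sirt7 and its neighbours Pcyt2, P4hb and Arhgdia in the 4 groups, with each dot 1 library, bars for the mean ± SD, and diamonds for the 2 libraries labelled KO-NT 4 and KO-GS 3. Sirt7 averages 20.3 CPM in WT-NT and 1.09 CPM in KO-NT, and Pcyt2 67.6 and 13 CPM.

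None of the lists that follow had a member called over all genes in this comparison with all libraries. Of 19 immediate early genes, which respond fast to growth factors and stress, 0 were called over all genes and 4 were higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000168; adjusted p = 0.523 with an estimated correlation). These were Klf2 at 1.04 (SE 0.24), Klf4 at 1.34 (SE 0.385), Fosl1 at 1.16 (SE 0.297) and Jun at 0.65 (SE 0.19), and camera gave 0.35 for the list without WT-NT 4, in a range of 1.92e-06 to 0.35. Of 20 glycolysis genes, 0 were higher or lower, also adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.000559; adjusted p = 0.523 with an estimated correlation). Of 12 adipocyte markers, 0 were higher or lower, also adjusted over the list alone, with a median of 0.74 (camera adjusted p = 0.00132; adjusted p = 0.523 with an estimated correlation), and camera gave 0.0824 without KO-NT 1, in a range of 7.99e-05 to 0.0824. Of 24 chaperones, 0 were called by either adjustment, also adjusted over the list alone, with a median of 1.01 (camera adjusted p = 0.000168; adjusted p = 0.64 with an estimated correlation). Camera gave 0.893 for them without the library labelled KO-NT 4, in a range of 9.35e-07 to 0.991. Of 75 ribosomal proteins, 0 were called by either adjustment, also adjusted over the list alone, with a median of 0.16 (camera adjusted p = 5.14e-07; adjusted p = 0.644 with an estimated correlation). Camera gave 0.0804 without WT-NT 4 and 0.156 without the library labelled KO-NT 4, in a range of 3.05e-16 to 0.202. H2afy had a log2 change of -0.18 (adjusted p = 0.968).

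The fourth comparison asks which genes SirT7 loss changes in starved cells. Sirt7 fell from 17.3 ± 0.373 CPM (SD, n = 3) to 0.39 ± 0.0872 CPM (SD, n = 3), a log2 change of -5.51 (SE 0.345, adjusted p = 1.73e-05), and was lower in all 3 SirT7-/- libraries. It was the only gene edgeR called, with 608 genes at an unadjusted p under 0.05. It was also the only one without the 2 libraries labelled KO-NT 4 and KO-GS 3. Of Sirt7's neighbours, Pcyt2 averaged 67.6 CPM in WT-NT and 15.9 CPM in WT-GS, and P4hb 1540 and 2430 CPM, so their wild-type levels differed between media. Between the genotypes in starved cells, Pcyt2 had a log2 change of -0.64 (adjusted p = 0.893), P4hb of 0.15 (adjusted p = 0.939) and Arhgdia of 0.51 (adjusted p = 0.893). With single libraries left out these values moved: Pcyt2 was at -1.29 without the library labelled KO-GS 3 and at -0.39 without KO-GS 2, Arhgdia at 0.11 without KO-GS 2, and P4hb at -0.23 without KO-GS 2 and 0.45 without the library labelled KO-GS 3. In the fit without the 2 libraries, Pcyt2 had a log2 change of -1.28 (SE 0.192, adjusted p = 0.312, in a range of 0.186 to 1). DESeq2 called 7 genes and limma-voom 1, and the edgeR count was 2 without WT-GS 3, KO-GS 1 or KO-GS 2. H2afy had a log2 change of -0.18 (adjusted p = 0.893).

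Of 10 epithelial markers in starved cells, 0 were called over all genes, and 4 were higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00959; adjusted p = 0.663 with an estimated correlation). The keratins Krt18 and Krt7 had log2 changes of 0.90 (SE 0.303) and 1.32 (SE 0.464). With 1 library left out, Krt18 ran from 0.701 to 1.044 and Krt7 from 0.455 to 1.633. Camera gave 0.0966 without WT-GS 3 and 0.198 without KO-GS 2, in a range of 4.89e-05 to 0.198. Of 15 macrophage markers, 0 were called by either adjustment, also adjusted over the list alone, with a median of 1.44 (camera adjusted p = 7.71e-06; adjusted p = 0.663 with an estimated correlation). Camera gave 0.364 without WT-GS 2, in a range of 1.4e-09 to 0.364. The mean log2 CPM of these markers was 5.20, 1.80 and 4.43 in KO-GS 1 to 3 and -1.55 in WT-GS 2. Of 75 ribosomal proteins, 24 chaperones and 23 sterol synthesis genes, 0 were called by either adjustment, also adjusted over the list alone, with medians of -0.22, -0.49 and 1.12. The camera adjusted p-values were 6.49e-11, 2.22e-06 and 1.35e-05, each with adjusted p = 0.663 with an estimated correlation. Without the library labelled KO-GS 3, camera gave 0.399 for the chaperones and 0.892 for the sterol genes, in ranges of 1.53e-10 to 0.399 and 1.2e-07 to 0.892.

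The fifth comparison asks whether the starvation response differs between the genotypes. No gene passed that test. Cxcl12, a chemokine, had the response 1.72 (SE 0.477, adjusted p = 0.68) higher on the log2 scale in SirT7-/- cells, and Pde1a, a phosphodiesterase, 1.29 (SE 0.335, adjusted p = 0.68). With 1 library left out, Cxcl12 ran from 1.122 to 1.952 and Pde1a from 1.109 to 1.462, and over all alternatives Cxcl12 went as low as 0.94. edgeR called 0 of 15666 genes, with 950 at an unadjusted p under 0.05, DESeq2 called 2, and limma-voom called 0, with 850 at an unadjusted p under 0.05. Without the 2 libraries labelled KO-NT 4 and KO-GS 3, edgeR called 0, with 524 at an unadjusted p under 0.05. The count was 1 without WT-GS 3 or KO-GS 1.

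In the difference between responses, 0 members of any list were called, also adjusted over the list alone. Camera called 17 lists, none of them with an estimated correlation. The 24 chaperones had a median difference of -1.53 (camera adjusted p = 3.27e-08; adjusted p between 0.656 and 0.804 with an estimated correlation for these 17 lists). The 35 stress response targets had a median of -0.54, the 23 sterol synthesis genes of 1.19 and the 30 G2 and M phase genes of 0.57. Without the 2 libraries, the chaperone median was -0.09 (camera adjusted p = 0.0654, in a range of 3.83e-11 to 0.138) and the stress response median -0.09 (camera adjusted p = 0.151, in a range of 4.71e-08 to 0.733). There camera's direction turned for the sterol list (adjusted p = 0.000735, in a range of 3.21e-06 to 0.165) and for the G2 and M phase list (adjusted p = 0.321, in a range of 2.19e-10 to 0.671). The 15 macrophage markers kept a median of 2.22 without the 2 libraries, against 2.26 with them, and the 18 muscle markers one of 1.68, against 1.69. The macrophage list's camera adjusted p ranged from 2.49e-08 to 0.0438. Its mean log2 CPM was -1.55 in WT-GS 2, against 3.63 and 3.54 in WT-GS 1 and 3. In KO-GS 2 it was 1.80, against 5.20 and 4.43 in KO-GS 1 and in the library labelled KO-GS 3. The muscle list's camera adjusted p was 0.0603 without KO-GS 2, in a range of 3.5e-10 to 0.0603, and KO-GS 2 had the highest mean of its group for that list, at 0.863 log2 CPM, against -1.27 and -1.04.

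Across genes, which are not independent replicates, the log2 changes of the genotypes' responses had a Pearson correlation of 0.522 (jackknife SE 0.284) and a Spearman correlation of 0.652. Without the 2 libraries these were 0.651 and 0.785. Of the 4063 genes called in wild type, 95.2% had the same sign in SirT7-/- cells, with a median ratio of 0.467 between the changes. Without the 2 libraries, these values were 98.6% of 6280 genes and 0.963. In that fit 4375 genes were called in both genotypes, all in the same direction. The 2 libraries were left out for their position along the wild-type starvation genes, so these values without them are not an independent measure of how alike the responses are.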

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

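The tests on label exchange, RNA mixture, libraries out of place by genotype, the Sirt7 locus and shared reads were chosen after the result was seen, while the counts over other splits of the samples were set beforehand.

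In KO-NT, 67 of 132 results had 1 library whose gap to its nearest neighbour exceeded what the Dixon test allows in 4 samples, and 18 of 132 did in WT-NT. Chance alone gives about 1 in 20. In KO-NT this was the library labelled KO-NT 4 for 54 of 56 genes and all 8 lists. Some of these genes were named from the fit that left that library out, and starvation genes move together, so the count cannot be set against that rate as a test. The gap as a share of the range was 1 for Derl3, Prr32, Dnajb9 and Eif3j1, 0.99 for Car6, Tnfsf18 and Herpud1, and 0.98 for Wnt7a, Ero1lb, Hspa5, B4galnt2, Ppef1, Ddit3 and Bnip3. It was 0.97 for Hsp90b1 and the chaperone list, 0.96 for Apol6, and 0.95 for Clic5, Canx, Rpl24, Ero1l, Sirt5, Perp and the autophagy list. It was 0.94 for Extl1, Emc6, Klf4, the total count and the transfer RNA synthetase list, and 0.93 for Slc7a1, Atg12, Stc2 and the G2/M and ribosomal protein lists. It was 0.92 for Ifitm1, Pno1, P4hb, the position along the starvation genes and the hypoxia list, and 0.91 for Slc6a12, Bub1b, Pde4a, Pdk1, Arhgdia and, through KO-NT 2, Sesn2. It was 0.89 for Tyms, Mcm5, Psph, Mdm2 and the sterol list, 0.88 for Becn1 and Heyl, and 0.87 for Cdc20 and the first principal component. It was 0.86 for Omd, Fads2 and Plk1, 0.85 for Arrdc4, Camk2d and the stress response list, 0.84 for Lrrc17, Noc3l and H2afy2, and 0.83 for Ano1 and, through KO-NT 1, Ccr2.

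In WT-NT, the gap was 0.95 for Clic5, 0.93 for Hspa5, 0.9 for Krt18, 0.88 for Perp, 0.87 for Dnajb9, 0.86 for Atg12 and Ppef1, and 0.84 for Mcm5 and Col24a1, all through WT-NT 4. The lists gave 0.88 for DNA replication, through WT-NT 4, and 0.92 for the glucose-driven genes, through WT-NT 3. The p53 list gave 0.94, through WT-NT 4, and the glycosylation list 0.87, through WT-NT 1. It was 0.87 for Ero1lb, 0.85 for Cxcl5 and 0.86 for Pcyt2 through WT-NT 2, 0.9 for F13a1 through WT-NT 3 and 0.85 for Emc6 through WT-NT 1.

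The library labelled KO-NT 4 lay closest to KO-GS 1 (correlation 0.9898), and the library labelled KO-GS 3 to WT-NT 4 (0.9884), beside which it also lay on the third principal component (54.7 and 64.4, with every other library at or under 9.59). Against a mixture of RNA from both media, the 22 genes that wild-type cells raise most gave the library labelled KO-GS 3 a median starved share of 2.83%, and the library labelled KO-NT 4 one of 105%. An exchange of the 2 labels stays open: 90.2% of the starvation genes in the library labelled KO-NT 4 and 72.7% in the library labelled KO-GS 3 lay nearer to the other medium's SirT7-/- libraries, and although 72.7 is under 75, a bound set as counting against exchange, that bound was dropped after the value was seen because WT-NT 4, whose own label was not tested, had 74.6% of genes nearer to its own medium. The library labelled KO-GS 3 had chaperone (6.80) and sterol (6.75) list means, in log2 CPM, like normal medium, but p53 target (6.32), autophagy (6.70) and replication (4.90) means like starved libraries, as WT-NT 4 did (6.28, 6.67 and 4.82), while its Sirt7 (0.393 CPM) and Arhgdia (661 CPM) lay outside KO-NT 1 to 3 (1.02 to 1.41, and 1537.1 to 1628.5). That SirT7 loss makes cultures miss or mimic the response also stays open: 2 of 7 SirT7-/- and 0 of 7 wild-type libraries were out of place (Fisher's exact test, two-sided, p = 0.462), but the starvation genes were chosen on the wild-type libraries, so the 0 was largely fixed and the test decides nothing.

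The differences in P4hb, Arhgdia and Pcyt2, next to Sirt7 on chromosome 11, may be local to the altered locus: without the 2 libraries labelled KO-NT 4 and KO-GS 3, 3 of the 20 nearest genes differed by at least 1 on the log2 scale, as many as in 0.75% of 10000 random windows, and with all libraries 2 did, as many as in 2.67%. Loss of SirT7 as such setting the level of Pcyt2 also stays open, as 0 SirT7-/- libraries, the 2 left aside, reached the lowest wild-type library of their medium. It stays open for Arhgdia too, where 1 such library, KO-GS 1, lay at or below the highest wild-type library of its medium, and 1 library excludes nothing. An earlier form of the Arhgdia test, over all 7 SirT7-/- libraries and both media, had 3 within the wild-type range, but 2 of these were the libraries out of place. How the locus was altered is not in the labels.

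Eif3j1, Atp6v0c and Fdx1l, chosen after their values were seen, went from near 0 to abundant within groups. Shared reads are a candidate explanation: the log2 sum with the partner feature had an SD over libraries of 0.187 for Eif3j1 with Eif3j2, 0.24 for Atp6v0c with Atp6v0c-ps2 and 0.468 for Fdx1l with Raver1-fdx1l. Eif3j1 alone spanned 8.81 on the log2 scale. No biological explanation was tested.

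Camera found 17 lists whose response differed between the genotypes with all libraries, none of them with an estimated correlation. Of these, without the libraries labelled KO-NT 4 and KO-GS 3, 7 kept their direction and call, 6 lost the call and 4 turned, and with WT-NT 4 left out as well 4 kept them, 9 lost the call and 4 turned. With all libraries, the adjusted p was 2.87e-14 for ribosomal proteins, 2.5e-12 for ribosome assembly, 3.27e-08 for chaperones, 1.76e-06 for stress response targets, 6.46e-06 for G2/M, 4.23e-05 for macrophage, 4.33e-05 for transfer RNA synthetase, 5.36e-05 for muscle, 8.77e-05 for sterol synthesis and 0.000296 for interferon genes. It was 0.00115 for immediate early, 0.00879 for second messenger, 0.023 for glycosylation, 0.0252 for Hox, 0.0349 for matrix, 0.046 for fatty acid synthesis and 0.0494 for imprinted genes. Over the alternatives with the preset correlation, camera's adjusted p ranged from 5.67e-15 to 1.65e-05 for ribosome assembly. For ribosomal proteins it ranged from 1.79e-22 to 0.733.

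For the wild-type response, 1 of 35 splits of the libraries gave as many genes, the labelled one (4063, highest other 2343). That share is under the bound of 0.05 set beforehand, but it is the smallest that 35 splits allow, so it is weak evidence against chance. The split with 2343 set WT-NT 4 with WT-GS 1 to 3 against WT-NT 1 to 3. For SirT7-/- starvation, all 35 of 35 splits gave at least the labelled count of 0, an outcome that a count of 0 fixes and that says nothing on chance. The highest other, 5393, set KO-NT 1 to 3 with the library labelled KO-GS 3 against the rest, which points to a structure of the samples. For SirT7 loss in normal medium, 3 of 35 splits gave as many (labelled 1, highest other 2), so chance cannot be excluded for a count of 1. This is about the count, not about Sirt7, the gene called, whose adjusted p was between 1.2e-59 and 0.0059 over the alternatives. For SirT7 loss in starved cells, the 10 splits are too few for a share under 0.05 (labelled 1, highest other 0). For the difference between responses, 50 of 50 splits gave at least the labelled 0 genes (highest other 0), which a count of 0 also fixes.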

How the results depend on the processing

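The fits without the 2 libraries labelled KO-NT 4 and KO-GS 3, or without these and WT-NT 4, were chosen after the result was seen, and the other alternatives were set beforehand. Counts of called genes were set against their reported value once per comparison and fit. They stayed within 1.5 times that value in 54 of 70 cases with 1 library left out. In other fits set beforehand this was 30 of 39 cases, and in added fits 2 of 10.

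For starvation in wild type, the count ranged from 0 to 5621 when 1 library was left out, and was 6280 without the 2 libraries and 7444 without the 3. For starvation in SirT7-/- the range was 0 to 3301, with 201 by DESeq2, 2644 with the replicate block, 5251 without the 2 libraries and 6291 without the 3. For SirT7 loss in normal medium the range was 1 to 3, with 19 by DESeq2, 3 by limma-voom, 2 with RLE, the stricter filter or the block, 4 without the 2 libraries and 5 without the 3. For SirT7 loss in starved cells the range was 1 to 2, with 7 by DESeq2 and 2 without the 3 libraries. For the difference between responses the range was 0 to 1, with 2 by DESeq2 and 1 without the 3 libraries (Ablim1, chosen after its value was seen). The correlation of the responses ranged from 0.332 to 0.608 with 1 library left out. It was 0.241 by DESeq2, 0.684 with the stricter filter, 0.787 over called genes, 0.651 without the 2 libraries and 0.702 without the 3. The DESeq2 value also covers genes that filterByExpr removed from the reported fit, so it differs in genes as well as in method. Leaving out libraries changes the number of samples. With the replicate block, WT-NT 4 and the library labelled KO-NT 4 have no starved library of their number. They therefore do not bear on the starvation changes in that fit. The cause of the other differences was not tested. The difference between responses has no fit on only the groups compared. Sample numbers were not shown to pair samples: in no pair of groups did every sample correlate best with its own number. With all libraries, the lowest same-number correlations were -0.101, 0.0352, -0.116 and -0.00609, and those between the starved groups were 0.298, 0.458 (the highest among same-number pairs) and 0.0352. A pair with different numbers, KO-NT 4 and KO-GS 1, had 0.461.

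In SirT7-/- starvation, the log2 change turned for Derl3 (-0.669), Car6 (-0.134) and B4galnt2 (-0.767) without KO-GS 1, for Arrdc4 (0.055 and 0.021) without KO-GS 1 or KO-GS 2, and for Col24a1 with library size alone (0.002), without KO-NT 1 (0.114) or KO-NT 2 (0.413), and without KO-GS 1 (0.539) or KO-GS 2 (0.486). P4hb turned in starved cells without KO-GS 2 (-0.228). With 1 library left out, these changes ranged from -0.669 to 8.122 for Derl3, -0.134 to 4.385 for Car6, -0.767 to 4.111 for B4galnt2, -3.437 to 0.539 for Col24a1, -1.759 to 0.055 for Arrdc4 and -0.228 to 0.451 for P4hb. The cause was not tested. The other single-gene results were counted once for each fit. In the other fits set beforehand, 939 of these kept direction and call, 23 gained and 22 lost the call. When 1 library was left out, 1367 kept them, 27 gained and 346 lost the call. In the added fits 172 kept them and 78 gained the call. A gene not called in the reported fit counts as kept while it stays uncalled in the same direction. These totals therefore say little on how stable the calls were. All losses with 1 library left out were in wild-type starvation. There 68 results lost the call in each of the fits without WT-GS 1, WT-GS 2, WT-GS 3 or WT-NT 3.

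Camera's direction turned for these lists, given by adjusted p. In wild type, the sirtuin, macroH2A and PARP list turned without WT-GS 2 (0.993) and without the 2 libraries (0.976). In SirT7-/- starvation, the matrix list turned without KO-GS 1 (0.783). There the stress response and ribosomal protein lists turned without KO-NT 4 (0.301, 0.664), without KO-GS 3 (0.0367, 0.183), without the 2 libraries (0.00101, 0.00988) and without the 3 (0.000502, 0.00814). For SirT7 loss in normal medium, the sterol list turned without KO-NT 4 (0.078), the 2 (9.28e-06) or the 3 (1.59e-09), and ribosomal proteins without the 3 (0.0643). For the difference between responses, G2/M (0.321), sterol (0.000735), matrix (0.147) and fatty acid lists (0.1) turned without the 2 libraries, and sterol (3.83e-06), Hox (0.733), matrix (0.0426) and fatty acid lists (0.076) without the 3. With 1 library left out, the adjusted p ranged from 0.656 to 0.993 for the sirtuin list in wild type, and in SirT7-/- starvation from 0.000618 to 0.783 for matrix, 0.0367 to 0.894 for stress response and 4.34e-05 to 0.664 for ribosomal proteins. It ranged from 0.00664 to 0.363 for the sterol list after SirT7 loss in normal medium. The cause was not tested. Other list results, counted once for each fit: 185 kept, 1 gained and 58 lost the call in the other fits set beforehand, 50 of the losses with an estimated correlation. When 1 library was left out, 775 kept, 21 gained and 51 lost it, and in the added fits 82 kept, 4 gained and 20 lost it. As for genes, a list not called in the reported fit counts as kept while it stays uncalled in the same direction.

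In simulated data with the depth and spread of all libraries, the test recovered 53% of 2-fold and 72.7% of 4-fold shifts for starvation in wild type, and 10.6% and 54.5% for the difference between responses. The simulation drew each gene on its own and held no library out of place. It also recovered 55.2% of 2-fold shifts for starvation in SirT7-/-, where the labelled data gave 0 calls. These shares therefore cannot be taken as the power in the real data.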

Other observations

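The sex-linked control genes showed 1 pattern in all 14 libraries. Xist, expressed from the inactive X chromosome, lay between 798 and 1590 CPM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a count of 0 in every library, which allows up to 0.0502 CPM in the shallowest. The macrophage markers in normal medium had a mean log2 CPM of 5.07, 4.28, 4.08 and 4.61 in KO-NT 1 to 4. The skeletal muscle markers had 0.257, 0.517, 0.988 and -0.295 in WT-NT 1 to 4 and -1.15, -1.14 and -1.11 in WT-GS 1 to 3.

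The date entries took 0.255 to 0.288% of the counts per library, and the genes behind them were not identified. The first principal components held 45.3, 14.1 and 10% of the variance.

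The fry test, which asks whether a list's genes move one way on balance, called 1 of 38 lists for starvation in wild type (adjusted p = 0.000344) and 1 for the difference between responses (adjusted p = 0.0174). Both times it was the glycosylation list, named here after its values were seen, with 6 of 16 genes higher and 2 lower in starved wild-type cells, also adjusted over the list alone (camera adjusted p = 0.0728; adjusted p = 0.678 with an estimated correlation). Camera gave 0.0482 without WT-GS 1, in a range of 0.0478 to 0.179. In the other comparisons fry called 0 lists, with smallest adjusted p-values of 0.334 for starvation in SirT7-/-, 0.335 for SirT7 loss in normal medium and 0.0585 in starved cells. A fit without the libraries labelled KO-NT 4 and KO-GS 3, chosen after the result was seen, had fry calls for 19 lists for starvation in each genotype and 0 in the other comparisons.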
